A study of Homo sapiens with 4 samples.

How the data were processed

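HCT116 is an established human colon carcinoma cell line. Per the labels, cells received PBS (the control), vitamin C, 5-Aza-CdR (5-aza-2'-deoxycytidine, an inhibitor of DNA methyltransferases) or both agents, called the combination here. Doses and exposure times are not given in the sources used here. Per the labels' protocols, total RNA was taken up in Trizol and treated with DNase I, ribosomal RNA was depleted, and libraries were made with a stranded kit. The 4 libraries fall into 4 groups with 1 library per treatment, so no value has a replicate error.

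Per the submitters' processing notes, the authors used TopHat2, Cuffdiff and the hg19 genome build, whose versions and settings are not given in the sources used here. The 6 deposited tables each compare 1 pair of libraries and have 59337 rows. Their values are FPKM (fragments per kilobase of transcript, scaled separately for each pair of libraries, as given below) as the authors deposited them, named only as values in the file headers. Each table also holds the authors' deposited log2 fold change, of the second-named over the first-named library, here PBS over treatment in the tables with PBS. Recomputed from the values, 0 rows with both values above 0 were off by more than 0.001, and all ratios below are turned to first over second. The authors' deposited p-value and q-value columns and significance calls stand in tables that each name 2 libraries, and are read as comparing those libraries and not the treatments. The labels give every library used here the number 2, and whether other libraries entered the authors' calls is not given in the sources used here. Whether strand was used in the counting is not stated, so values of genes that overlap another gene on either strand are uncertain. Histone, metallothionein, interferon lambda and ribosomal protein genes have near-identical copies, so their values are uncertain too. A locus in these tables can span several overlapping genes. Reads were not used here, so whether a high value of a single gene comes from whole transcripts or from short isoforms or small RNAs within the locus was not tested.

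The tables were scaled separately. The PBS values of the table with vitamin C were 0.890 times those of the table with 5-Aza-CdR, and the 5-Aza-CdR values of the table with the combination were 1.16 times those of the table with PBS. All ratios therefore come from within 1 table, except the departure from additivity. Absolute depth is unknown. The commonest ratio of low values at loci without a symbol gave relative depths of 1.37 for the 5-Aza-CdR library, 1.04 for the vitamin C library and 1.11 for the combination library, each against the PBS library. These are ratios of what 1 fragment was worth in FPKM within 1 table, so they hold its scaling. They equal relative sequencing depth only where scaling followed depth.

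Rows without a gene symbol (31730 of 59337) were counted separately. For rows with a symbol, 1 row was kept per symbol, the one with the highest mean FPKM, and rows with the status FAIL or HIDATA were left out. Loci with several symbols entered the gene counts and no list. Genes with at least 1 FPKM in either library entered a comparison, so a gene silent in 1 library entered only by its value in the other. Ratios are log2 ratios of FPKM plus a pseudocount of 1, which understates the change of low genes, and folds given for single genes are plain FPKM ratios. With 1 library per group no test between libraries was run, and the only p-values used were the authors'. A gene counted as higher or lower at a difference of at least 2-fold. The 24 gene lists were fixed before the data were examined, as were the comparisons, the size rule and the rule for named genes. They held interferon-stimulated genes, double-stranded RNA sensing and signalling, antigen presentation, cancer-testis and germline genes, promoter-methylated genes of colorectal cancer, DNA methylation and demethylation enzymes, p53 targets, cell cycle, antioxidant response and iron, vitamin C transport, hypoxia-inducible factor targets, iron- and 2-oxoglutarate-dependent dioxygenases, genes derived from endogenous retroviruses, imprinted genes, colon epithelial, fibroblast and blood cell markers, the stress and unfolded protein response, mitochondrially encoded, ribosomal protein, replication-dependent histone, C2H2 zinc finger, microRNA and small nucleolar RNA host and housekeeping genes. Each list with at least 5 passing members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in deciles. A list was called at a percentile of at most 2.5 or at least 97.5, as a description of these libraries. The authors' deposited p-values were also adjusted over the list alone by Benjamini-Hochberg at 0.05, which is not a call of the authors and compares libraries as theirs do.

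Named genes were the 6 with the highest and the 6 with the lowest ratio among genes called in the authors' deposited table (filled up by size with uncalled genes where fewer were called), up to 3 members of each list with the largest absolute ratio, and a set of interferon, methylation, p53, redox and reference genes always named. For the comparisons against vitamin C, 3 per direction were taken. Some of them are not reported here, and not all others are given one by one. Small RNAs, recognised by the first symbol of a locus, were left out of the named genes. Transcript lengths came from GENCODE v29 by gene symbol, for 85.4% of the 13767 genes with a single symbol that passed in 5-Aza-CdR against PBS.

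The size rule was tested on simulated data built from the PBS values, with a log2 scatter of 0.15 and 12872 genes, for 5-Aza-CdR against PBS. The changed genes had at least 5 FPKM. It called 100% of 50 genes changed 3-fold and 100% of 50 genes changed 8-fold, 0% of 50 genes changed 1.5-fold and 0% of 12672 unchanged genes. Of 40 unchanged lists of 40 genes, 2 were called, and of 40 lists shifted by 0.3 on the log2 scale, 40 were called. These outcomes follow from the assumed scatter and check the computation only, not the error between single libraries. Alternatives were a pseudocount of 0.1 FPKM, no filter (for lists other than the interferon-stimulated genes added after the data were seen), a filter of 5 FPKM, ratios centred on the median gene, small RNAs left out by the first symbol, by any symbol or by all symbols of a locus, the mean of the interferon-stimulated list, the authors' call, and values of the same library in the other tables. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.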

Results

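Total RNA depleted of ribosomal RNA was measured in HCT116 colon carcinoma cells given PBS, vitamin C, 5-Aza-CdR or both agents, with 1 library per treatment. The design asks how each agent and the combination differed from the PBS control, and how the combination differed from each single agent. Calls quoted from the authors' deposited tables compare libraries, not conditions. In the 4 comparisons of a library with 5-Aza-CdR against one without it, the median log2 ratio of all genes lay between -0.25 and -0.24, so list medians are given relative to the median of all genes.

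In the 5-Aza-CdR library, cancer-testis genes and interferon-stimulated genes stood far above the PBS library, and ribosomal protein genes and genes of the stress and unfolded protein response stood below it. MAGEA4, a cancer-testis antigen gene (hg19 chromosome X, 151081361 to 151093642), was listed at 0 in PBS and at 51.6 FPKM after 5-Aza-CdR. IFI27, an interferon-induced gene (chromosome 14, 94577079 to 94583036), was 32.0-fold higher, at 232 against 7.24 FPKM. GDF15, a secreted stress cytokine gene (chromosome 19, 18496968 to 18499986), was 19.8-fold lower, at 8.88 against 176 FPKM. Of 14218 genes, 845 were at least 2-fold higher and 729 at least 2-fold lower, and relative to the median gene the split was 1060 and 356.

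Of 65 cancer-testis and germline genes with a locus of their own in the table, 45 passed the filter, 39 of them only by their value after 5-Aza-CdR. Among the 45, 40 were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.0 (percentile 100 of matched random lists). Of the 6 with at least 1 FPKM in PBS, 2 were at least 2-fold higher. Of the 59 under 1 FPKM in PBS, 54 had a higher and 1 a lower value after 5-Aza-CdR, against 6585 and 1609 of all 10883 such genes with a single symbol. Without a filter the uncentred median was 1.66 (percentile 100). By the authors' deposited table, 16 cancer-testis genes rose, and 24 passed when the authors' p-values were adjusted over the list alone. PAGE5 was listed at 0 in PBS and at 33.0 FPKM, and TKTL1 stood at 53.9 against 0.168 FPKM. Of 29 genes known for promoter methylation in colorectal cancer, 10 were higher and 4 lower by the size rule, around a median of 0.59 (percentile 99.99). Of the 29, 10 passed only by their value after 5-Aza-CdR, and of the 19 with at least 1 FPKM in PBS, 4 were at least 2-fold higher and 4 lower. UCHL1, a deubiquitinase gene (chromosome 4, 41258898 to 41270446), was listed at 0 in PBS and at 46.8 FPKM. SPARC stood at 14.97 against 1.65 FPKM and SFRP1, a WNT antagonist gene, at 3.12 against 0.0119 FPKM. The list of genes derived from endogenous retroviruses had a median of 0.47 (percentile 99.67), and 5 of 15 passed only by their value after 5-Aza-CdR. This list, kept under that name below, also holds genes that come from other retrotransposons. Among them were PNMA5, at 30.5 against 0.0197 FPKM, and PEG10, 9.55-fold higher. With a filter of 5 FPKM the uncentred medians of the promoter-methylated and the retrovirus-derived lists were below 0, at -0.058 and -0.44, where that of all genes was -0.30.

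Of 47 interferon-stimulated genes, 33 were at least 2-fold higher and 0 lower, and the median was 1.58 (percentile 100). By the authors' deposited table, 2 rose, IFI27 and IFI6, and 13 passed when adjusted over the list alone. Of the 47, 9 passed only by their value after 5-Aza-CdR, and of the 38 with at least 1 FPKM in PBS, 24 were at least 2-fold higher. IFI6 (chromosome 1, 27992572 to 27998724) stood at 426 against 58.1 FPKM, with a q of 0.0287 in the authors' deposited table. MX1, an antiviral GTPase gene, was 17.1-fold higher, OAS1 10.4-fold and ISG15 4.07-fold, all uncalled in the authors' deposited table. Genes of double-stranded RNA sensing and signalling had a median of 0.42 (percentile 100), with 8 of 28 at least 2-fold higher. Of the 28, 5 passed only by their value after 5-Aza-CdR, and of the 23 with at least 1 FPKM in PBS, 3 were at least 2-fold higher. Uncentred, and with a filter of 5 FPKM, the median of this list was -0.026, against -0.30 for all genes. IFIH1 (MDA5) stood at 19.7 against 7.22 FPKM, DDX58 (RIG-I) at 19.7 against 6.05 FPKM and IRF7, a transcription factor of the interferon response, at 48.7 against 16.8 FPKM, while the adaptor gene MAVS stood at 20.3 against 26.7 FPKM. TLR3 was listed at 0.433 against 0.0629 FPKM. Of 19 antigen presentation genes, 3 were at least 2-fold higher, with a median of 0.52 (percentile 100) and CD74 at 3.53 against 0.645 FPKM. Among these 19, 4 passed only by their value after 5-Aza-CdR, and of the 15 with at least 1 FPKM in PBS, 1 was at least 2-fold higher.

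Of 79 ribosomal protein genes, 32 were at least 2-fold lower and 3 higher, with a median of -0.72 (percentile 0). The higher members were the paralogs RPL39L and RPL10L, both listed at 0 in PBS, and RPL3L. RPLP0 stood at 965 against 2272 FPKM. Replication-dependent histone genes were split, with 33 of 62 at least 2-fold lower and 23 at least 2-fold higher, around a median of -0.89 (percentile 0). Of these 62, 17 passed only by their value after 5-Aza-CdR, and among the 45 with at least 1 FPKM in PBS, 33 were lower and 7 higher. Over all 62 the uncentred median was -1.13 and the uncentred mean 0.19, so these differ in sign. HIST1H4A stood at 51.4 against 659.7 FPKM, while HIST1H4F and HIST1H1B were listed at 0 in PBS and at 23.0 and 20.7 FPKM after 5-Aza-CdR. By the authors' deposited table, 3 histone genes fell and 8 rose, and 20 lower and 9 higher ones passed when adjusted over the list alone. Of 32 genes of the stress and unfolded protein response, 12 were at least 2-fold lower and 0 higher, with a median of -0.52 (percentile 0.01). TRIB3, a pseudokinase gene of the ATF4 response, was 7.76-fold lower, DDIT4, an inhibitor of mTORC1 signalling, 7.54-fold and PHGDH, an enzyme of serine synthesis, 7.17-fold. These genes, GDF15 and TMEM42, at 8.62 against 182 FPKM, fell in the authors' deposited table. Whether the value of TMEM42 in PBS comes from the whole transcript was not tested.

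Medians of further lists without a call were 0.057 for DNA methylation and demethylation enzymes (percentile 86.67), -0.093 for p53 targets (18.57), -0.13 for hypoxia-inducible factor targets (10.2) and 0.082 for iron- and 2-oxoglutarate-dependent dioxygenases (94.27). Imprinted genes lay at 0.17 (96.52), zinc finger genes at 0.092 (94.31), microRNA and small nucleolar RNA hosts at -0.47 (6.48) and housekeeping genes at -0.016 (83.92), also without a call. Without a filter, imprinted genes (percentile 99.98) and zinc finger genes (100) were called higher and the host genes (0.93) lower. Cell cycle genes at 0.15 (percentile 99.92) and antioxidant and iron genes at 0.13 (99.48) were called higher, although their uncentred medians were -0.092 and -0.11. DNMT3B stood at 12.04 against 5.09 FPKM, DNMT1 at 35.1 against 56.6 FPKM, CDKN1A at 41.0 against 48.4 FPKM and MKI67 at 48.3 against 43.8 FPKM. The 5 passing vitamin C transport genes had a median of 0.65 (percentile 99.25), with SLC2A3 at 6.81 against 2.73 FPKM. Among passing genes, markers of other cell types and of colon epithelium stood higher beside these groups. Here 16 fibroblast and mesenchymal genes had a median of 0.79 (percentile 100), 13 blood cell genes 1.29 (99.83) and 18 colon epithelial genes 0.42 (99.66). Of 27 fibroblast and 27 blood cell genes in the table, 4 and 8 passed only by their value after 5-Aza-CdR, and of the 12 and 5 with at least 1 FPKM in PBS, 3 and 1 were at least 2-fold higher. Without a filter the uncentred medians were 0.30 (percentile 100) and 0.49 (99.93), and colon epithelial genes, at 0.066 (90.64), were no longer called. CD3D, a T cell receptor complex gene, stood at 3.97 against 0.101 FPKM and THY1 at 3.74 against 0.413 FPKM, and SPARC belongs to the fibroblast as well as the promoter-methylated list. The tables give the mitochondrial genome as 1 locus without a symbol, so the list of mitochondrially encoded genes held 0 genes. Of 773 calls in the authors' deposited table, 743 had a value of 0 in 1 of the libraries. At loci with a symbol 240 rose and 14 fell in the authors' deposited table, and 14 and 14 did with values above 0 in both libraries.

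**Figure D1:**
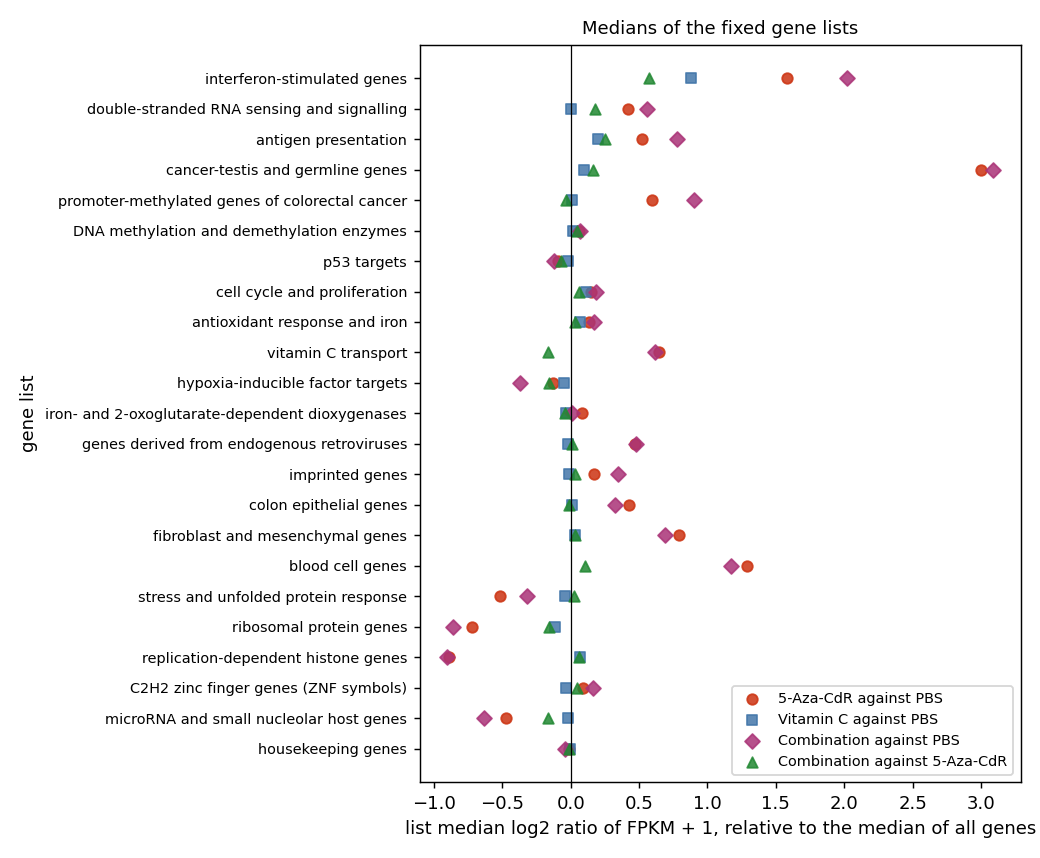
Median log2 ratio of FPKM + 1 of each fixed gene list, relative to the median of all genes (horizontal), by list (vertical), with 1 marker per comparison and none where fewer than 5 genes of a list passed. Cancer-testis genes lay at 3.0 and 3.09 for 5-Aza-CdR and the combination against PBS, and interferon-stimulated genes lay above 0 in the 4 comparisons shown.

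In the vitamin C library, interferon-stimulated genes stood above the PBS library, while of the other lists only those of double-stranded RNA sensing, with 3, and histone genes, with 1, held a gene at least 2-fold higher or lower. IFI6 was 4.34-fold higher at 225 against 51.8 FPKM, IFI27 4.31-fold at 27.8 against 6.45 FPKM, IFITM1 3.70-fold, IFIT1 3.70-fold and ISG15, a ubiquitin-like antiviral protein gene (chromosome 1, 948847 to 949919), 3.04-fold. These 5 genes rose in the authors' deposited table, each with a q of 0.0239. Of 41 interferon-stimulated genes, 19 were at least 2-fold higher and 0 lower, with a median of 0.88 (percentile 100). Of the 41, 3 passed only by their value after vitamin C, and of the 38 with at least 1 FPKM in PBS, 18 were at least 2-fold higher. By the authors' deposited table, 22 of the 41 rose, and 33 passed when adjusted over the list alone. After 5-Aza-CdR these counts were 2 and 13 at a higher median of 1.58, so counts of calls do not rank the comparisons by size of change.

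IRF7 (chromosome 11, 612555 to 615999) stood at 36.4 against 15.04 FPKM, IFIH1 at 16.6 against 6.41 FPKM and OAS1 at 3.94 against 0.882 FPKM, and these 3 genes rose in the authors' deposited table. DDX58 stood at 15.1 against 5.36 FPKM and MX1 at 1.61 against 0.632 FPKM, uncalled there. Genes of double-stranded RNA sensing and signalling had a median of -0.00038 (percentile 49.99), with 3 of 24 at least 2-fold higher. Antigen presentation genes had a median of 0.20 (percentile 100), with 0 of 15 at least 2-fold higher and PSMB9, an immunoproteasome subunit gene, at 2.41 against 1.30 FPKM.

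Only 6 cancer-testis genes passed the filter, with a median of 0.098 (percentile 97.55) and 0 at least 2-fold higher. MAGEA3 stood at 9.37 against 8.25 FPKM. Cell cycle genes had a median of 0.11 (percentile 100), with PCNA at 71.3 against 53.3 FPKM, and antioxidant and iron genes 0.069 (99.96), with the metallothionein gene MT1E at 451 against 316 FPKM. Ribosomal protein genes lay at -0.11 (percentile 0) and hypoxia-inducible factor targets at -0.051 (0.49), with 0 and 0 genes at least 2-fold lower. Zinc finger genes, at -0.032 (percentile 0), were also called lower, and histone genes, at 0.068 (99.98), higher. The TET genes, whose enzymes use vitamin C as a cofactor, stood at 2.68 against 2.96 FPKM for TET1, 4.68 against 4.97 FPKM for TET2 and 9.19 against 9.55 FPKM for TET3. HMOX1 stood at 7.72 against 7.98 FPKM and the vitamin C transporter gene SLC23A2 at 10.8 against 11.6 FPKM.

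Of 13177 genes, 103 were at least 2-fold higher and 94 lower, but without small RNAs the counts were 41 and 13. Named genes with large positive ratios included DLG4, at 421 against 10.2 FPKM, and HEATR6, at 123.5 against 11.5 FPKM, which rose in the authors' deposited table. HIST1H1T, a testis histone gene, also rose in the authors' deposited table, at 10.3 against 3.85 FPKM. The 3 passing calls of lower genes in the authors' deposited table were small RNAs or loci of several genes, so the lower genes named by size were uncalled, among them STIM1, at 6.31 against 531 FPKM, and SCRIB, at 29.9 against 156 FPKM. Whether the values of DLG4, HEATR6, STIM1 and SCRIB come from whole transcripts or from short isoforms or small RNAs within the locus was not tested, since reads were not used here.

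**Figure D2:**
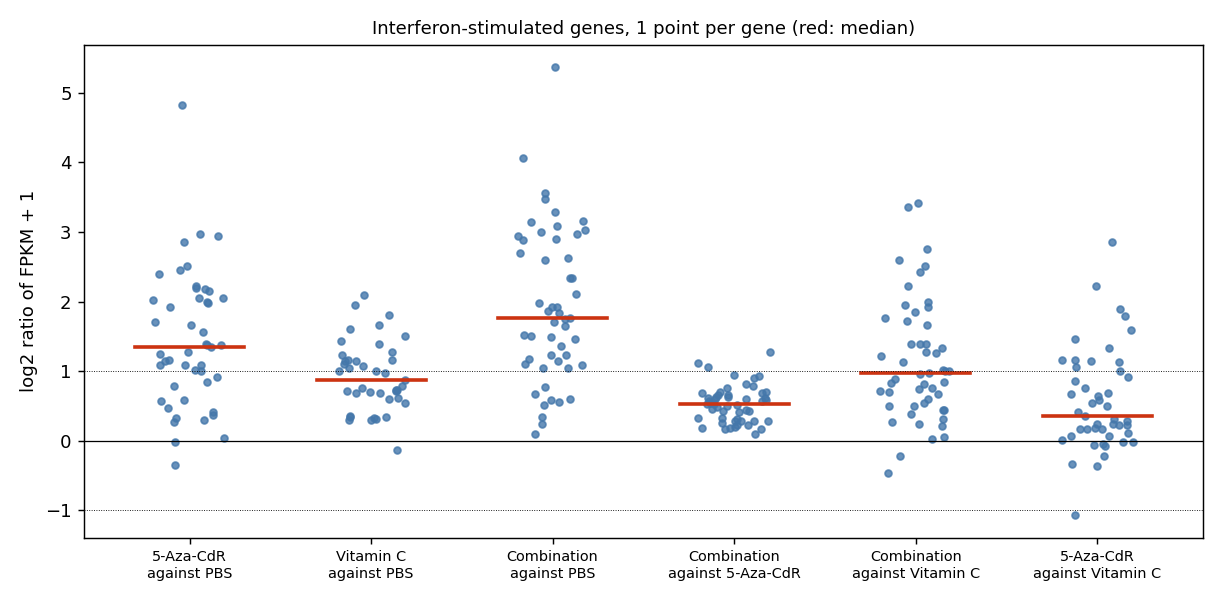
Log2 ratio of FPKM + 1 (vertical), not centred, of each passing interferon-stimulated gene in the 6 comparisons (horizontal), with 1 point per gene, a red line at the median and dotted lines at 2-fold. From left to right the medians were 1.35, 0.87, 1.76, 0.53, 0.98 and 0.36.

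The combination library held higher interferon-stimulated and cancer-testis genes and lower ribosomal protein genes than the PBS library. IFI27 was 47.0-fold higher at 341 against 7.25 FPKM, MX1 39.1-fold, OAS1 16.8-fold, IFI6 11.3-fold and ISG15 6.07-fold. MAGEA4 and UCHL1, both listed at 0 in PBS, stood at 53.1 and 79.1 FPKM. DDIT4 was 10.2-fold lower and ASNS, the asparagine synthetase gene (chromosome 7, 97481429 to 97501854), 7.36-fold lower at 29.9 against 220.2 FPKM. Of 14380 genes, 963 were at least 2-fold higher and 1059 lower, and relative to the median gene the split was 1249 and 514.

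Of 51 interferon-stimulated genes, 42 were at least 2-fold higher and 0 lower, with a median of 2.02 (percentile 100). By the authors' deposited table, 4 rose, among them IFI27, IFI6 and ISG15, and 29 passed when adjusted over the list alone. Of the 51, 13 passed only by their value in the combination, and of the 38 with at least 1 FPKM in PBS, 29 were at least 2-fold higher. Genes of double-stranded RNA sensing and signalling had a median of 0.56 (percentile 100) and antigen presentation genes 0.78 (100). In these lists, 5 and 4 genes passed only by their value in the combination. Of the 23 and 15 with at least 1 FPKM in PBS, 3 and 4 were at least 2-fold higher. IFIH1 stood at 31.0 against 7.23 FPKM, DDX58 at 32.3 against 6.06 FPKM, IRF7 at 64.7 against 16.8 FPKM and the interferon lambda gene IFNL1 at 6.64 against 0.377 FPKM, all uncalled in the authors' deposited table. Of 46 passing cancer-testis genes, 40 of which passed only by their value in the combination, 42 were at least 2-fold higher and 15 rose in the authors' deposited table (21 passed when adjusted over the list alone), with a median of 3.09 (percentile 100). Promoter-methylated genes lay at 0.90 (percentile 100), with CHFR, a mitotic checkpoint gene, listed at 0 in PBS and at 2.85 FPKM. Of 30 such genes 11 passed only by their value in the combination, and of the 19 with at least 1 FPKM in PBS, 4 were at least 2-fold higher and 3 lower. With a filter of 5 FPKM the uncentred median of the promoter-methylated list was -0.23, and that of the double-stranded RNA list -0.013, where that of all genes was -0.32.

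Of 79 ribosomal protein genes, 55 were at least 2-fold lower, with a median of -0.86 (percentile 0). Histone genes lay at -0.90 (percentile 0; uncentred median -1.16, mean 0.26), with 32 lower and 23 higher of 62. Among the 45 histone genes with at least 1 FPKM in PBS, 32 were lower and 7 higher. Hypoxia-inducible factor targets lay at -0.37 (percentile 0.03), with 9 of 41 at least 2-fold lower and VEGFA at 13.7 against 53.7 FPKM. Genes of the stress and unfolded protein response lay at -0.32 (percentile 2.79, not called, but 1.18 and called without a filter), with 12 of 32 at least 2-fold lower. ASNS, DDIT4, TRIB3, SAT1 and HIST1H1E fell in the authors' deposited table, and GDF15 stood at 6.77 against 176 FPKM, uncalled. Imprinted genes lay at 0.35 (percentile 99.89) and genes derived from endogenous retroviruses at 0.48 (99.3), the latter at -0.45 uncentred with a filter of 5 FPKM. Fibroblast and mesenchymal genes lay at 0.69 (percentile 99.97) and blood cell genes at 1.17 (99.7), or uncentred without a filter at 0.32 and 0.41. UBAP2, at 999.8 against 21.2 FPKM, rose in the authors' deposited table, and whether its value comes from the whole transcript was likewise not tested.

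Set against 5-Aza-CdR alone, the combination library held higher interferon-stimulated genes. IFIT2 was 2.54-fold higher at 29.4 against 11.5 FPKM, MX1 2.24-fold at 31.5 against 14.1 FPKM, IFIT3 2.19-fold and SAMD9 2.13-fold. These genes rose in the authors' deposited table, with q values of 0.0249, 0.0249, 0.0453 and 0.0249. Of 51 interferon-stimulated genes, 3 were at least 2-fold higher and 0 lower, with a median of 0.57 (percentile 100), and 26 higher ones passed when the authors' p-values were adjusted over the list alone. The interferon lambda genes stood at 7.52 against 3.20 FPKM for IFNL1, 3.55 against 1.41 FPKM for IFNL2 and 5.12 against 2.46 FPKM for IFNL3, uncalled in the authors' deposited table.

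Genes of double-stranded RNA sensing and signalling lay at 0.18, antigen presentation genes at 0.25 and cancer-testis genes at 0.16 (each at percentile 100), while promoter-methylated genes lay at -0.035 (percentile 12.08). Hypoxia-inducible factor targets lay at -0.16 (percentile 0), with ALDOC at 16.2 against 26.6 FPKM, ribosomal protein genes at -0.16 (0) and p53 targets at -0.070 (0.68), with no member of these lists at least 2-fold lower. Cell cycle genes at 0.062 (percentile 99.73), histone genes at 0.057 (99.97) and zinc finger genes at 0.047 (100) were also called higher. No member of these 3 lists was at least 2-fold higher. DNMT1 stood at 40.8 against 40.7 FPKM, DNMT3B at 13.4 against 13.96 FPKM, TET1 at 3.67 against 4.53 FPKM and TET2 at 4.99 against 5.26 FPKM. KRT17, a keratin gene, was 2.37-fold higher and rose in the authors' deposited table. LRWD1, at 33.1 against 165 FPKM, fell in the authors' deposited table. The lower genes added by size, MTRNR2L9, MTRNR2L2, RAB11FIP4 and C15orf48, the last at 0.545 against 139 FPKM, were uncalled there. Whether the values of LRWD1, RAB11FIP4 and C15orf48 come from whole transcripts was not tested either. Of 14481 genes, 105 were at least 2-fold higher and 96 lower, but without small RNAs the counts were 15 and 24.

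Against vitamin C alone, cancer-testis genes stood higher and ribosomal protein genes lower in both libraries with 5-Aza-CdR. In the combination the medians were 3.06 for cancer-testis genes, 1.22 for interferon-stimulated genes (each at percentile 100) and -0.75 for ribosomal protein genes (percentile 0). In the 5-Aza-CdR library they were 3.0, 0.60 and -0.60, at the same percentiles. Of the passing cancer-testis genes, 40 of 46 and 38 of 45 passed only by their value in the library with 5-Aza-CdR. Fibroblast and mesenchymal genes stood at 0.72 (percentile 99.94) in the combination and 0.87 (99.99) after 5-Aza-CdR, and blood cell genes at 1.07 (99.6) and 1.23 (99.9). Colon epithelial genes stood at 0.27 (95.88, not called) and 0.38 (99.45). HIST1H4F was listed at 0 after vitamin C, at 31.8 FPKM in the combination and at 23.1 FPKM after 5-Aza-CdR. DDIT4 and TRIB3 were 9.48-fold and 7.39-fold lower in the combination, and GDF15 and HIST1H4A 17.4-fold and 12.6-fold lower in the 5-Aza-CdR library, and all of them fell in the authors' deposited tables. The combination had 911 genes at least 2-fold higher and 917 lower than vitamin C (1194 and 446 relative to the median gene), and 5-Aza-CdR had 786 and 708 (1006 and 344).

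Each agent was given without and with the other, so its contrast can be read in 2 pairs of libraries that share none. For 5-Aza-CdR, 674 genes were at least 2-fold higher in both pairs and 577 lower in both, where independent lists would share 44.9 and 44.4, and 30 differed in opposite directions, against 89.9. These counts were uncentred. Centred on the median gene, 252 were lower in both, and uncentred with a filter of 5 FPKM 235 were higher in both. Across 13992 genes, which are not replicates, Pearson's r of the log2 ratios was 0.75 and Spearman's rho 0.91. Of 47 interferon-stimulated genes, 21 were at least 2-fold higher in both pairs. For vitamin C, 40 of 41 interferon-stimulated genes had a ratio above 0 in both pairs, and 2, IFIT2 and IFIT3, were at least 2-fold higher in both. Across all 12899 genes r was 0.21 and rho 0.31, with 16 genes at least 2-fold higher and 18 lower in both pairs, where independent lists would share 0.349 and 0.276. About as many, 31, differed at least 2-fold in opposite directions, where independent lists would share 0.621. Without small RNAs, 7 genes with a single symbol and 1 locus of several symbols had opposite directions. In the same direction, 4 and 3 were left by the first symbol of each locus, the higher ones being IFIT2, IFIT3, PLEKHJ1 and LOC101929613, and the lower ones LINC00159, SCRIB and the locus of LOC553103 and MIR3936. Of these, PLEKHJ1, LOC101929613 and LOC553103 were named after their values were seen. Leaving out any locus with a small RNA symbol gave 4 and 2, and leaving out only loci with no other symbol gave 5 and 3.

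**Figure D3:**
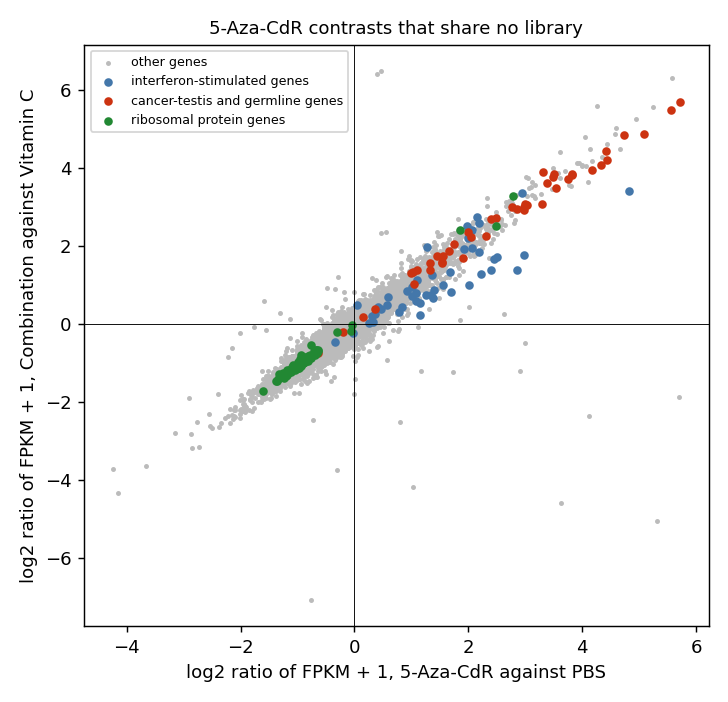
Log2 ratios of FPKM + 1 for 5-Aza-CdR against PBS (horizontal) and the combination against vitamin C (vertical), with 1 point per gene, small RNAs left out and interferon-stimulated genes in blue. Cancer-testis genes (red) had uncentred medians of 2.76 and 2.82, and ribosomal protein genes (green) -0.96 and -0.99.

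**Figure D4:**
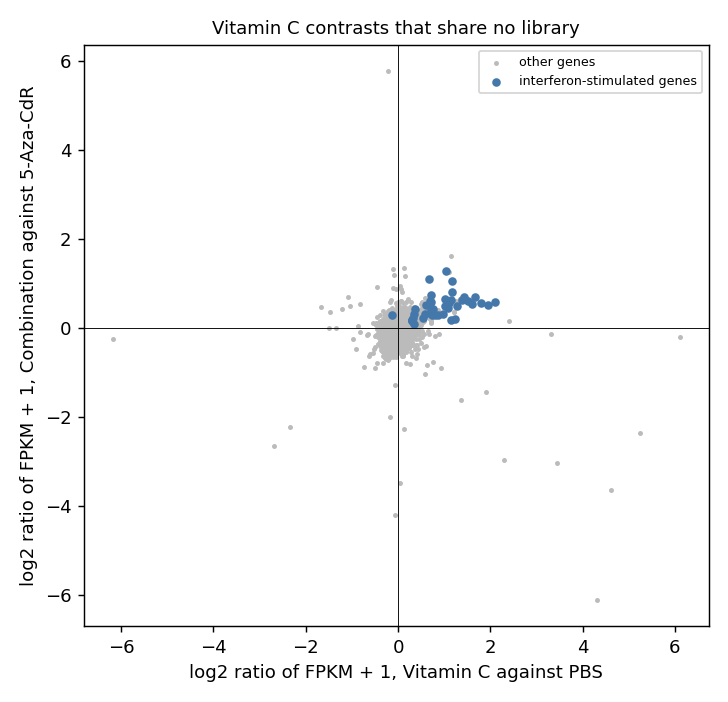
Log2 ratios of FPKM + 1 for vitamin C against PBS (horizontal) and the combination against 5-Aza-CdR (vertical), with 1 point per gene and small RNAs left out. Interferon-stimulated genes (blue) lay above 0 in both pairs of libraries for 40 of 41 genes.

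The combination was also set against the sum of the single agents on the log2 scale, with values from separately scaled tables and the PBS library in each of them. Interferon-stimulated genes lay below the sum, with a median departure of -0.21 (percentile 0), and 16 of 51 lay above it, or 7 with a pseudocount of 0.1 FPKM. IFI6 departed by -1.47 and ISG15 by -1.02. A sum of log2 ratios is a product of folds. A gene below it can still gain as much FPKM as under both single agents together, and additivity in FPKM was not computed. Genes of double-stranded RNA sensing and signalling departed by 0.070 (percentile 99.72), which turned to -0.0098 with a pseudocount of 0.1 FPKM. Hypoxia-inducible factor targets departed by -0.12 (percentile 0), and histone genes by -0.084 (1.18). Zinc finger genes departed by 0.069 (percentile 100, 249 of 365 above the sum) and imprinted genes by 0.069 (99.13). Cancer-testis genes, at 0.041 (percentile 96.71), had no call, and neither did the other lists with at least 5 genes.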

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

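Except for the comparison of medians with genes matched on transcript length and level, the tests in this part were chosen after the results were seen.

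Interferon-stimulated genes stood above PBS in the vitamin C library. Their median was 0.88 after centring, as given above (quartiles 0.62 and 1.17), where a difference in scaling would leave about 0. Centring could move this median little, since the median of all genes was -0.0058. Against carry-over from a library with 5-Aza-CdR, 44 genes silent in PBS reached a median of 0.177% of their combination value in the vitamin C library. The highest was 5.45% for XAF1, itself an interferon-stimulated gene, and the next was 3.21% for FAM50B. By carry-over alone, 45 interferon-stimulated genes would need 25.7% (quartiles 12.5 and 39.9%). The combination against 5-Aza-CdR, a pair of other libraries, gave a median of 0.57 (0.53 uncentred). With 1 library per treatment, however, variation between single cultures cannot be told apart from the treatment. An effect of vitamin C on these genes stays open as a hypothesis.

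Ribosomal protein genes stood lower after 5-Aza-CdR, and histone genes went both ways. After centring, ribosomal protein genes stayed at -0.72 (quartiles -0.92 and -0.57), and 30 of 62 histone genes were at least 2-fold lower while 24 were at least 2-fold higher, where 1 factor would move all alike and at least 10 each way were asked for. All 68 histone genes without a filter gave 30 and 24, the 55 with a mean of at least 5 FPKM 30 and 18, and the 54 passing ones above 0 in both libraries 30 and 16, but the 45 with at least 1 FPKM in PBS 30 and only 7, fewer than asked for. Uncentred, other genes matched on transcript length and level had a median of -0.31 (95% of lists between -0.43 and -0.19) against -0.96 for ribosomal protein genes. The uncentred median of -0.23 matched to histone genes decides nothing, since these went both ways. Of 60 histone genes, 33 were at least 2-fold lower, also uncentred, where matched lists held 3 (95% between 1 and 7). The match was imperfect, since the genes matched to ribosomal protein genes had a median of 407 against 993 FPKM, and a response of the cells to 5-Aza-CdR was not tested and stays open.

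Loci without a symbol, which no comparison above uses, held 496 loci at least 2-fold higher and 207 lower after 5-Aza-CdR, and 790 and 241 in the combination. The share listed at 0 was 1.42% after 5-Aza-CdR and 1.73% in the combination against 26.2% in PBS, and among loci with a symbol 15.7% and 15.7% against 23.5%. If the relative depths above held, deeper sequencing alone would leave at least 21.0% and 24.3% without a symbol, and 20.9% and 22.5% with one. Those depths come from the scaling of each table and need not equal sequencing depth, so these bounds cannot exclude deeper sequencing. Loci without a symbol were at 0 in PBS 18.5 times as often as after 5-Aza-CdR, and loci with one 1.496 times, so a candidate explanation is that these loci were defined from reads of the libraries with 5-Aza-CdR. Wider transcription after 5-Aza-CdR stays open, and DNA left in the RNA was not tested.

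The ratio of 5-Aza-CdR to its control had opposite directions without and with vitamin C, at least 2-fold each, for 8 genes with a single symbol other than small RNAs, and that of vitamin C without and with 5-Aza-CdR for 7, and these differences were not tested. Among loci of several symbols without a small RNA, 1, of AMH and SF3A2, did so for both agents, at log2 ratios of -3.21 and 3.23 for 5-Aza-CdR and -2.26 and 4.14 for vitamin C. DLG4 stood at 647 FPKM after 5-Aza-CdR against 11.4 in PBS, but at 129 FPKM in the combination against 472 after vitamin C. RAB11FIP4 stood at 192 against 3.85 FPKM and at 1.98 against 97.3 FPKM, and CEMP1, UBA7, ZBTB20 and TMCC3 also belonged to both sets. These 4 genes and the locus of AMH and SF3A2 were named after their values were seen. Whether these values come from whole transcripts or from short isoforms or small RNAs within the loci was not tested, since reads were not used here.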

How the results depend on the processing

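No paired analysis was possible because each treatment has 1 library and all libraries carry the same number, so neither leaving out a replicate nor a replicate block gave a value. A fit of both agents as additive terms over the 4 libraries, which would leave 1 residual degree of freedom, was not run. Adding loci without a symbol, list medians without a filter other than that of interferon-stimulated genes, leaving out histone and ribosomal protein genes, counting the authors' calls only where both libraries were above 0, leaving out small RNAs from the counts shared by both pairs, the rules for loci that hold a small RNA among several symbols, and both alternatives for the departure from additivity were chosen after seeing the data. The cause of a change was not tested, except that a filter of 5 FPKM tests fewer genes. Absolute depth is unknown, so no counting interval is given.

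Medians of interferon-stimulated, cancer-testis and ribosomal protein genes kept their direction and call in each comparison under each alternative run, although for cancer-testis genes in vitamin C against PBS a filter of 5 FPKM left fewer than 5 genes and no value. For interferon-stimulated genes they ranged from 0.69 to 1.11 in vitamin C against PBS and from 1.68 to 2.23 in the combination against PBS. Of 533 alternative list medians 483 kept their call, and their direction where called. Of these, 128 came from centring, which moves all genes alike and could change a direction but not a call. Of 772 alternative ratios of named genes 754 stayed on their side of 2-fold, 378 of them under centring. Named genes were in part chosen by the size of their ratio, which favours staying on 1 side. No filter on low values, and leaving out histone and ribosomal protein genes, moved no gene count by over 1.5 times, but neither could. Values both under 1 FPKM cannot differ 2-fold with the pseudocount of 1, and the histone and ribosomal protein genes were few beside the counts.

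In the order 5-Aza-CdR, vitamin C and combination against PBS, combination against 5-Aza-CdR, combination against vitamin C and 5-Aza-CdR against vitamin C, the authors' call in place of the size rule gave 101, 30, 97, 9, 85 and 87 higher genes, and 14, 3, 6, 5, 6 and 15 lower genes. At loci with a symbol, passing or not, the authors called 240, 32, 188, 9, 148 and 206 higher, of which 14, 31, 11, 9, 10 and 12 had values above 0 in both libraries, and 14, 3, 6, 6, 6 and 15 lower, of which 14, 3, 6, 5, 6 and 15 did. With loci without a symbol counted as well, the counts of genes at least 2-fold higher were 1341, 179, 1753, 326, 1690 and 1274, and of genes at least 2-fold lower 163 in vitamin C against PBS and 252 in the combination against 5-Aza-CdR. Without small RNAs vitamin C against PBS had 41 higher and 13 lower genes, and the combination against 5-Aza-CdR 15 and 24, by the first symbol of a locus. Leaving out any locus with a small RNA symbol gave 40, 12, 14 and 23, and leaving out only loci with no other symbol 42, 13, 17 and 25. In the 4 comparisons of a library with 5-Aza-CdR against one without, a filter of 5 FPKM left 360, 420, 388 and 326 higher genes, and centring 356, 514, 446 and 344 lower genes. A pseudocount of 0.1 FPKM gave 1139 lower genes for 5-Aza-CdR against PBS, 1408 for the combination against vitamin C and 1110 for 5-Aza-CdR against vitamin C. In both contrasts of 5-Aza-CdR, 235 genes were higher with the filter of 5 FPKM, and 923 were lower with the pseudocount of 0.1 FPKM and 252 when centred. In both contrasts of vitamin C, 4 higher and 3 lower genes were left without small RNAs by the first symbol, 4 and 2 without any locus with a small RNA symbol, and 5 and 3 without loci of small RNAs alone.

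Called uncentred list medians that changed sign did so by centring, the filter of 5 FPKM or, for zinc finger genes, no filter. With the filter of 5 FPKM the median of all genes lay between -0.32 and -0.30 in the 4 comparisons of a library with 5-Aza-CdR against one without, and of the filtered medians that changed sign only those of genes derived from endogenous retroviruses lay under it. All values with this filter or none were uncentred. Centring gave cell cycle genes 0.15 and 0.18 for 5-Aza-CdR and the combination against PBS, antioxidant and iron genes 0.13, 0.17 and, for the combination against vitamin C, 0.097, and zinc finger genes 0.16 for the combination against PBS and 0.20 and 0.15 for the combination and 5-Aza-CdR against vitamin C. Without a filter zinc finger genes came to 0.084, 0.10 and 0.056 in these 3 comparisons. The filter of 5 FPKM gave double-stranded RNA sensing genes -0.026 and -0.013 for 5-Aza-CdR and the combination against PBS and -0.085 for 5-Aza-CdR against vitamin C. It gave promoter-methylated genes -0.058 and -0.23 against PBS, and -0.18 and -0.044 for the combination and 5-Aza-CdR against vitamin C. Genes derived from endogenous retroviruses came to -0.44 and -0.45 against PBS and -0.50 for 5-Aza-CdR against vitamin C, where antigen presentation genes came to -0.060 and imprinted genes to -0.076. The departure from additivity of double-stranded RNA sensing and signalling was -0.0098 with a pseudocount of 0.1 FPKM and, without a call, 0.0074 with a filter of 5 FPKM.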

Other observations

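Some genes of the redox, colon and imprinted lists had large ratios after 5-Aza-CdR that the authors' deposited tables did not call. MT1G, a metallothionein gene, stood at 13.0 against 0.151 FPKM after 5-Aza-CdR and at 26.2 against 0.151 FPKM in the combination. CBR1, a carbonyl reductase gene, stood at 7.64 against 0.0129 FPKM after 5-Aza-CdR, and the imprinted gene FAM50B at 4.54 against 0.0373 FPKM. AXIN2, a WNT target gene, stood at 11.5 against 3.14 FPKM and KRT20, a keratin of differentiated colon epithelium, at 4.63 against 0.329 FPKM. SLC7A11, the cystine transporter gene, was 6.05-fold lower after 5-Aza-CdR.

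Other genes had far higher values in 1 library of a pair. UBAP2 stood at 1010.0 FPKM in the combination and 20.0 FPKM after vitamin C. HEATR6 stood at 139 FPKM after vitamin C and 10.4 FPKM after 5-Aza-CdR. Whether these values come from whole transcripts or from short isoforms or small RNAs within the loci was not tested, since reads were not used here.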
